A study of Mus musculus with 7 samples.

How the data were processed

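Gene expression was measured in quadriceps femoris muscle of mice that carried a transgene for a mutant form of Twinkle, the mitochondrial DNA helicase, and of wild-type mice. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made from 5 ug of it. Each sample was hybridised to 1 single-colour Affymetrix expression array, with 3 mutant arrays and 4 wild-type arrays. The labels call the arrays of a group biological replicates and give ages of 21 to 26 months. Groups and replicate numbers were taken from the sample titles. The free-text descriptions of all 7 samples name cerebellum, whereas the titles, the source and the tissue entries name muscle. The muscle entries were used, and markers of both tissues were measured.

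The deposited table holds log2 values for 45101 probe sets on 7 arrays, each expressed relative to that probe set's median over the 7 arrays. This reading comes from the values, in which the median was exactly 0 in all 45101 probe sets and no value was missing. The submitters' processing notes name GCOS 4.0. The summary method, the scaling of the arrays to each other and the step that centred the values were not given in the sources used here. Because of the centring, the deposited values hold differences between arrays and no levels, and each array's median was 0. A rough level was recovered from the spacing of the single-precision numbers, which widens with the size of the number before centring. On the log2 scale the median array lay between 8 and 16 for 7107 probe sets (15.8%), between 4 and 8 for 18780 (41.6%) and between 2 and 4 for 19166 (42.5%), and 48 stayed unresolved. The log base of 2 is read from this spacing, which has the steps of numbers between 2 and 16, and is not stated in the sources used here. Arrays give no read depth, so the number of arrays limits the precision.

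Probe sets were named through the platform annotation, which is old, and symbols were updated by Entrez identifier with a RefSeq gene table of the assembly GRCm38.p6. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were unnamed. The identifier matched the gene table for 34754 of the 34958, and 204 kept the annotation's symbol. Probe sets with several symbols or none and the 64 control probe sets were left out of the tests, which left 18193 genes. For the 9010 genes with more than 1 probe set, the gene's value was the mean of its probe sets in the highest recovered level class. No coordinates are given because the files name no genome build.

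Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, 3 mutant arrays against 4 wild-type arrays, two-sided, with no covariate and no filter on dim genes. Adjusted p-values are Benjamini-Hochberg values over the 18193 genes, and the threshold was 0.05. Errors of log2 fold changes are limma's standard errors. The design written before the data were examined took each gene's brightest probe set and a variance trend on the mean level. Centring removed the levels, so the rule above and a constant prior variance were used instead, and the trend was run as an alternative. The values of about 17 genes, Fgf21 and Twnk among them, were seen while the number spacing was studied, before any test was run.

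The 34 gene lists, 10 of them markers of cell types or sources, were fixed before the data were examined. Of 711 list entries, 666 were measured here. Lists were tested with limma's camera, a test of whether the genes of a list moved further in 1 direction than the other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 34 lists. The same test with an estimated correlation, limma's fry, and an exact two-sided permutation test of the list's mean per array over the 35 splits of 7 arrays into 3 and 4 were run beside it. The smallest p this permutation test can give is 0.0286. Within each list, p-values were also adjusted over the list alone. A list's mean difference is given with its SE over arrays.

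The text names genes by a rule fixed before the data were examined. It takes up to 10 genes per direction past the threshold with no overlap between groups, of which there were none. It always takes Fgf21, which the series title names, and Twnk, the gene of the transgene. In each list it takes the 2 to 4 members with the smallest p, and up to 10 past the threshold. Genes outside this rule are said to be chosen after their values were seen.

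The fit was tested on simulated data for this comparison, with 18193 genes, independent noise of each gene's own spread and 200 shifted genes. A log2 shift of 0.5 was recovered in 14.0% of genes, a shift of 1 in 64.0%, a shift of 2 in 90.0% and a shift of 3 in 94.0%. Of 17993 unshifted genes, 7 were called. Both lists shifted by 0.3 were called, and 1 of 32 unshifted lists was called. The simulated genes were uncorrelated, so these list counts do not test the preset correlation of 0.01. The shares of genes recovered also hold only for uncorrelated noise with 200 shifted genes. In the real lists the estimated correlation reached 0.757, in the slow muscle fibre list.

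The 7 arrays were compared before they were averaged. No 2 arrays were identical, and the highest correlation between 2 arrays over the centred gene values was 0.489. Alternatives were quantile normalization, a shift of every array to 1 median, the mean over all probe sets of a gene, each probe set on its own, a robust trended prior, array weights, age as a covariate, the replicate number as a block, both other list tests, and leaving out each array in turn. Alternatives added after the data were seen were a block for 3 arrays that stood apart from the other 4, the first component of the deviations from the group means as a covariate, a trended prior, a filter to genes with a recovered level of 4 or more, leaving out 2 wild-type arrays together, and the exact permutation test of list means. Quantile normalization acted on the centred gene values, so it gave every array the same spread of deviations. It does not test the normalization of intensities. All per-sample columns of the table were used.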

Results

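The series profiled quadriceps muscle from 3 mice with a mutant Twinkle transgene and 4 wild-type mice, with 1 array per mouse. Twinkle is the helicase that unwinds mitochondrial DNA during replication, and its mutation causes progressive external ophthalmoplegia, a mitochondrial muscle disease that this mouse line models. The mutant mice were 24, 24 and 21 months old and the wild-type mice 26, 24, 21 and 23 months. The series title names a starvation response and the hormone FGF21, so the comparison asks which genes and gene groups differ between mutant and wild-type muscle. All 10 muscle fibre markers lay in the highest recovered level class, between 8 and 16 on the log2 scale, while none of the 10 measured cerebellum markers did. Of these, 5 lay between 4 and 8 and 5 between 2 and 4. The levels are those of different probe sets, so they compare the tissues only roughly. Values are log2 values relative to each probe set's median over the 7 arrays, as deposited, so they show differences between arrays and not levels.

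Fgf21 and Mthfd2 measured higher in mutant than in wild-type muscle, with all 3 mutant arrays above all 4 wild-type arrays for both genes. Fgf21, a hormone released under metabolic stress, measured 1.26 ± 0.66 (SD, n = 3) in mutant and -0.22 ± 0.22 (SD, n = 4) in wild-type muscle, a log2 fold change of 1.48 ± 0.29 (SE) or 2.79-fold. Mthfd2, a mitochondrial enzyme of one-carbon metabolism, measured 1.13 ± 0.79 (SD, n = 3) and -0.38 ± 0.18 (SD, n = 4), a log2 fold change of 1.52 ± 0.33 or 2.86-fold. The genes of the integrated stress response were higher as a group by 0.27 ± 0.09 (SE) on the log2 scale, and 24 of the 26 measured had a positive difference (camera adjusted p = 7.74e-06, and adjusted p = 0.379 with an estimated correlation). No gene passed the threshold over all 18193 genes tested.

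With limma, 0 genes had an adjusted p under 0.05 in either direction, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 264 genes, 137 higher and 127 lower in mutant muscle, where 910 are expected if no gene differs and p-values are uniform. All 3 mutant arrays lay above all 4 wild-type arrays for 155 genes and below them for 218, where chance gives 520 genes per direction. The limma camera test with its preset correlation called 9 of the 34 lists, all higher in mutant muscle, where 13 had an unadjusted p under 0.05. Camera called 0 lists at a smallest adjusted p = 0.379 with an estimated correlation (3 lists at an unadjusted p under 0.05), fry called 0 (3 lists unadjusted), and the exact permutation test of list means called 0 (2 lists unadjusted). These 2 were the integrated stress response and satellite cell lists. For the other lists called by the preset camera test, the exact permutation p ran from 0.0571 to 0.714. Without mutant replicate 2 the preset camera test called 1 list, the integrated stress response. On simulated independent noise with 200 shifted genes, the same fit called 90.0% of genes shifted by a log2 value of 2. That noise lacked the correlation between real genes, and the adjusted threshold depends on how many genes are shifted. The 90.0% is therefore not the power of the real comparison.

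**Figure D1:**
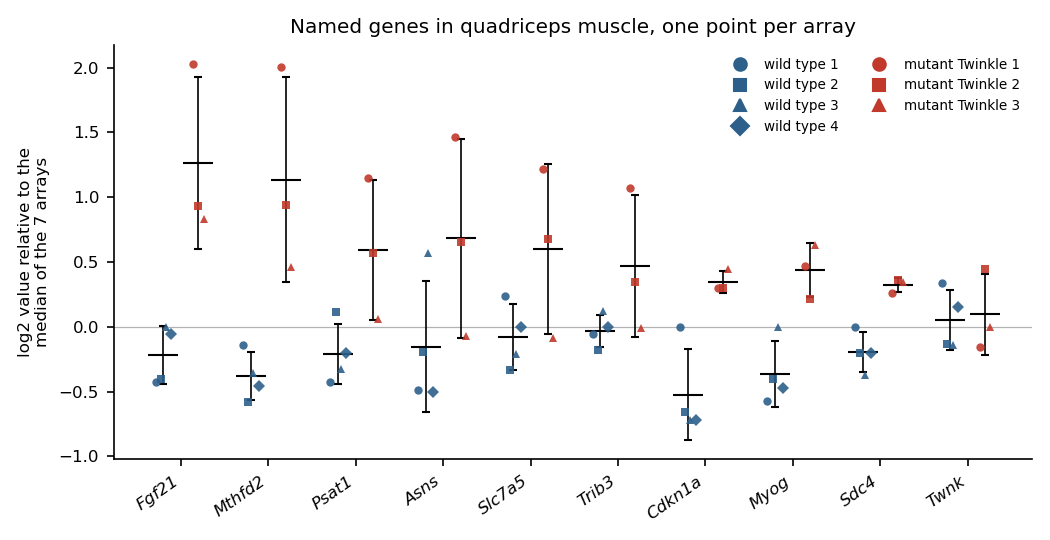
Log2 values relative to the median of the 7 arrays (vertical axis) for 10 named genes, with 1 point per array, wild type in blue and mutant Twinkle in red, and black bars at the group mean ± SD. Fgf21, Mthfd2, Cdkn1a, Myog and Sdc4 have all 3 mutant arrays above all 4 wild-type arrays, while Twnk overlaps.

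The integrated stress response, which raises ATF4 and its amino acid genes when translation or mitochondria are disturbed, had the strongest list call. Its 26 measured genes of 27 averaged 0.18 ± 0.13 (SD, n = 3) in mutant and -0.09 ± 0.08 (SD, n = 4) in wild-type muscle (camera adjusted p = 7.74e-06, and adjusted p = 0.379 with an estimated correlation). The list means were 0.34, 0.10 and 0.10 in the mutant arrays and -0.12, -0.01, -0.05 and -0.19 in the wild-type arrays. The exact permutation p was 0.0286, the smallest these arrays can give, and the permutation adjusted p over the 34 lists was 0.486. Fgf21 rose with the p-values adjusted over the list alone (adjusted p = 0.0320), and the other 25 members did not pass. Slc7a5, an amino acid transporter, had a log2 fold change of 0.68 ± 0.30, Asns, the asparagine synthetase, 0.84 ± 0.40, and Trib3, a pseudokinase induced by ATF4, 0.50 ± 0.24. In these 3 genes mutant replicate 1 was highest, at 1.22, 1.47 and 1.07, and mutant replicate 3 lay at -0.09, -0.07 and -0.01, within the wild-type range. The control probe sets for 18S ribosomal RNA averaged 3.19 in mutant replicate 1, against -0.77 to 0.56 in the other 6 arrays. Without mutant replicate 1 the difference was 0.37 for Slc7a5, 0.44 for Asns and 0.20 for Trib3. Leaving out any 1 array kept this list past the threshold, and without mutant replicate 1 the difference was 0.19.

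Enzymes of serine, one-carbon, proline and transsulfuration metabolism did not pass as a list of 19 measured genes (camera adjusted p = 0.563). Mthfd2 rose with the p-values adjusted over the list alone (adjusted p = 0.0427), and the other 18 did not pass. Psat1, which makes phosphoserine on the way to serine, had a log2 fold change of 0.80 ± 0.25. Without mutant replicate 1 the difference was 1.08 for Mthfd2 and 0.53 for Psat1. The list's mean difference was 0.08 and the median over its genes -0.05, so these differ in sign. The 18 measured cytosolic tRNA synthetases, which charge amino acids onto tRNA and include ATF4 targets, averaged 0.14 ± 0.11 (SE) higher (camera adjusted p = 0.00301, and adjusted p = 0.601 with an estimated correlation). None of the 18 passed when adjusted over the list alone, and the smallest p-values were those of Hars at 0.38 ± 0.19 and Aars at 0.23 ± 0.12. A second Hars probe set in a lower level class differed by 0.07. Without mutant replicate 2 or without wild-type replicate 3 the difference of this list was 0.06 in both cases and the call was lost (adjusted p = 0.248 and 0.242). The list mean was -0.28 in wild-type replicate 3, where the 5 prime minus 3 prime value of the Gapdh control, a sign of RNA quality, was -0.55 against at least -0.040 in the other 6 arrays. The same value of the beta-actin control was not low there, at 0.12 against -0.14 to 0.12 in the other 6. Adipocyte, leukocyte, fibroblast and nerve marker means were also highest in this array, as given below, and no cause was tested.

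Mitochondrial protein quality control and translation genes were called as lists with small differences. The 18 measured mitochondrial chaperones and proteases averaged 0.11 ± 0.04 (SE) higher (camera adjusted p = 0.00727, and adjusted p = 0.379 with an estimated correlation). Dnaja3, a mitochondrial co-chaperone, differed by 0.29 ± 0.13 and Oma1, an inner membrane protease, by 0.26 ± 0.13, and none of the 18 passed when adjusted over the list alone. This call was lost without mutant replicate 2 (difference 0.09, adjusted p = 0.132) and without wild-type replicate 1 (difference 0.07, adjusted p = 0.0797). The 76 measured mitochondrial ribosomal protein genes averaged 0.06 ± 0.11 (SE) higher (camera adjusted p = 0.0163, and adjusted p = 0.942 with an estimated correlation). Mrpl40 differed by 0.23 ± 0.08 and Mrpl45 by 0.36 ± 0.16, and 0 of the 76 passed when adjusted over the list alone. The difference was -0.03 without wild-type replicate 1, and the call was also lost without mutant replicate 2 (difference 0.09, adjusted p = 0.132), mutant replicate 3 (0.03, adjusted p = 0.165) or wild-type replicate 4 (0.03, adjusted p = 0.0914). It was 0.11 without wild-type replicate 2, 0.13 without wild-type replicate 3 and -0.00 without wild-type replicates 1 and 2 together. With age as a covariate it was 0.03 and the call was lost (adjusted p = 0.145). With 3 arrays that stood apart as a block the call was lost too (adjusted p = 0.258). The difference was -0.08 within the other 4 arrays and 0.17 within these 3.

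Respiratory chain and fuel oxidation genes were not called. The mean difference was 0.02 ± 0.08 (SE) over 35 complex I genes, 0.03 ± 0.16 over 29 genes of complexes III and IV, 0.02 ± 0.10 over 21 genes of complexes II and V, -0.02 ± 0.07 over 22 genes of the citric acid cycle and pyruvate dehydrogenase, and -0.02 ± 0.20 over 28 genes of fatty acid uptake and oxidation, with camera adjusted p from 0.408 to 0.758. The fatty acid uptake and oxidation list was called as lower without wild-type replicate 1 (adjusted p = 0.000277). In these 5 lists 0 genes passed when adjusted over the list alone. The members with the smallest p were Ndufa5 (0.14 ± 0.09) and Ndufb10 (0.13 ± 0.10) of complex I, Cox5a (-0.10 ± 0.08) and Sco1 (0.20 ± 0.17) of the complex IV group, Atpaf1 (0.18 ± 0.14) and Atp5e (-0.13 ± 0.13) of the ATP synthase group, Me2 (-0.27 ± 0.16) and Dlat (-0.10 ± 0.09) near the citric acid cycle, and Crat (-0.22 ± 0.14) and Acot1 (-0.24 ± 0.20) in fatty acid handling. The probe sets averaged for Crat gave differences of -0.03 and -0.42. The 23 genes of mitochondrial DNA maintenance and biogenesis averaged 0.04 ± 0.18 higher (camera adjusted p = 0.147), and were called with 3 arrays that stood apart as a block (adjusted p = 0.0147), with the mean over all probe sets (adjusted p = 0.0450), and without mutant replicate 1 (adjusted p = 0.00759), wild-type replicate 1 (adjusted p = 0.00971) or wild-type replicate 4 (adjusted p = 0.0439). Among them Ppargc1b lay at 0.21 ± 0.11 and Rrm2b, a subunit of ribonucleotide reductase, at 0.29 ± 0.17. Twnk measured 0.10 ± 0.31 (SD, n = 3) in mutant and 0.06 ± 0.23 (SD, n = 4) in wild-type muscle, a log2 fold change of 0.04 ± 0.18. The labels call the mutant mice overexpressors of mutant Twinkle, but Twnk did not pass, with -0.15, 0.44 and 0.00 in the mutant arrays and -0.14 to 0.34 in wild type. Whether its 1 probe set detects the transgene's transcript is not given in the sources used here.

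Genes of fasting and FoxO-driven atrophy were called as a list of 27 measured genes, which averaged 0.15 ± 0.09 (SE) higher (camera adjusted p = 0.00727, and adjusted p = 0.379 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, had a log2 fold change of 0.87 ± 0.19 or 1.83-fold. It did not pass when adjusted over this list alone (adjusted p = 0.0535), and it rose in the 16 measured cell cycle and DNA damage genes with the p-values adjusted over the list alone (adjusted p = 0.0317). A second probe set of Cdkn1a in a lower level class differed by 0.68 ± 0.26, with the mutant range overlapping that of wild type. Mt2, a metallothionein, differed by 0.60 ± 0.24, Ctsl, a lysosomal protease, by 0.36 ± 0.15, and Foxo1 by 0.16 ± 0.09. Probe sets in lower level classes gave 0.02 for Ctsl and 0.03, -0.14 and 0.09 for Foxo1. The call was lost without mutant replicate 2 (adjusted p = 0.162) and without mutant replicate 3 (adjusted p = 0.129), at a difference of 0.12 in both cases. The cell cycle and DNA damage list was not called (camera adjusted p = 0.0511), but it was with quantile normalization (adjusted p = 0.0449), the mean over all probe sets (adjusted p = 0.0172), age as a covariate (adjusted p = 0.0266) and without wild-type replicate 1 (adjusted p = 0.000823), and its next gene, Mki67, differed by 0.27 ± 0.18, or by 0.08 without mutant replicate 1.

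**Figure D2:**
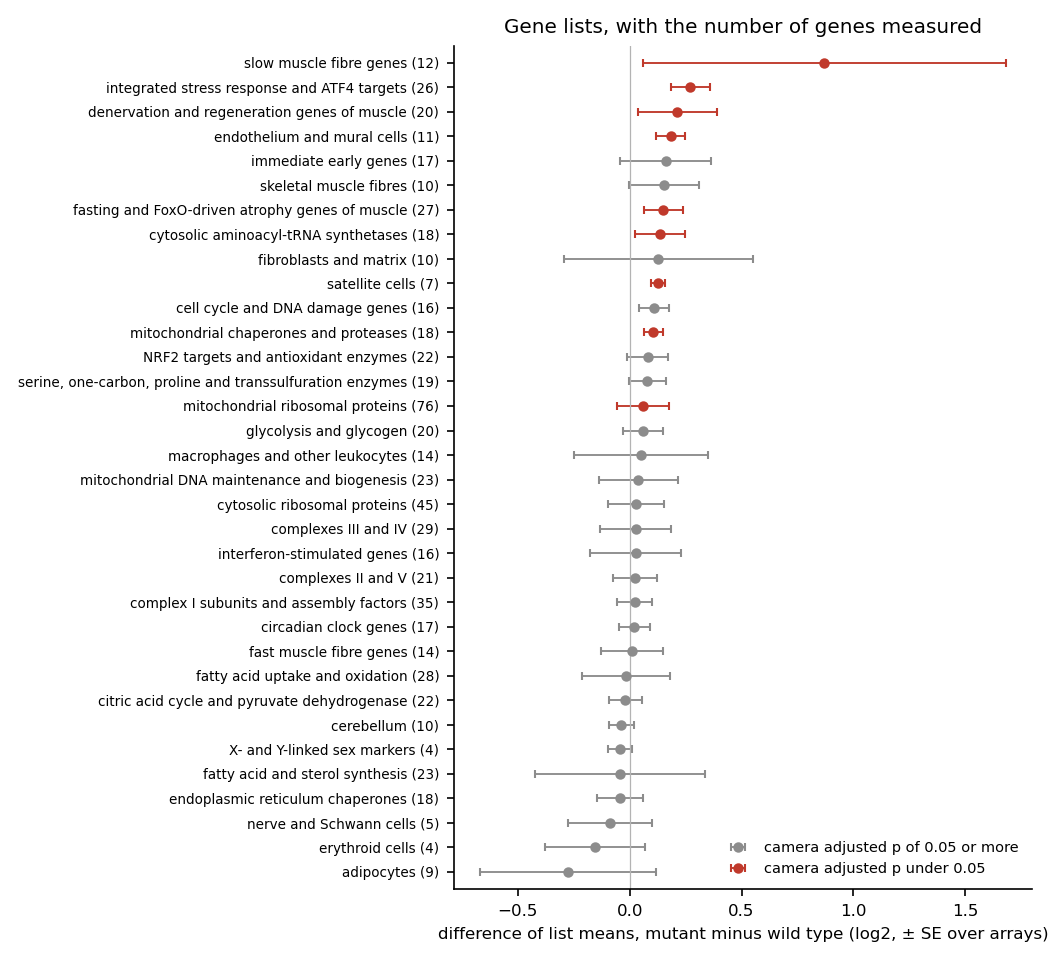
Difference of list means, mutant minus wild type, on the log2 scale (horizontal axis) for the 34 lists, with the number of measured genes in brackets, bars of ± 1 SE over arrays, and lists with a camera adjusted p under 0.05 in red. The stress response list lies at 0.27 ± 0.09, and the slow fibre list at 0.87 ± 0.81 has the widest bar.

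Slow muscle fibre genes, which encode the contractile proteins of oxidative fibres, averaged 0.87 ± 0.81 (SE) higher in mutant muscle over 12 genes (camera adjusted p = 0.0114, and adjusted p = 0.941 with an estimated correlation). The list means were 0.21, 0.00 and -0.08 in the mutant arrays and -2.70, -1.63, 0.55 and 0.48 in the wild-type arrays, so 2 wild-type arrays lay far below and 2 above every mutant array. Myh7, the slow myosin heavy chain, lay at -4.24 and -3.19 in wild-type replicates 1 and 2 and at 0.17 and 0.91 in replicates 3 and 4. Tnnt1, the slow troponin T, lay at -4.29 and -2.88 in the first pair. Without both of these arrays, a choice made after the values were seen, the list difference turned to -0.47 and the list was called as lower in mutant muscle (camera adjusted p = 4.13e-09). Leaving out only 1 array also ended the call, with differences of 0.79 without mutant replicate 1 (adjusted p = 0.164), 0.89 without mutant replicate 2 (adjusted p = 0.127), 0.24 without wild-type replicate 1 (adjusted p = 0.465) and 0.60 without wild-type replicate 2 (adjusted p = 0.225). It was 1.33 without wild-type replicate 3 and 1.31 without wild-type replicate 4. Members did not pass when adjusted over the list alone, with Myh7 at 1.64 ± 1.24, Tnnt1 at 1.54 ± 1.19, Myl2 at 1.26 ± 1.00 and Myl3 at 1.29 ± 1.14. The 14 fast fibre genes averaged 0.01 ± 0.14 (camera adjusted p = 0.758), with Myh2 at 0.10 ± 0.14 and Casq1 at -0.11 ± 0.16. The 10 general muscle fibre markers averaged 0.16 ± 0.16 (camera adjusted p = 0.121), with Ttn at 0.61 ± 0.33 and Ryr1 at 0.49 ± 0.31, and their list mean was -0.55 in wild-type replicate 3 against at least -0.05 in the other 6 arrays. In that array the 5 prime minus 3 prime value of the Gapdh control was -0.55 against at least -0.040 in the other 6. That of beta-actin was not low, at 0.12 against -0.14 to 0.12. Wild-type replicate 3 also had the highest adipocyte (1.01), leukocyte (0.74), fibroblast (1.04) and nerve (0.48) marker means of the 7 arrays. Its erythroid (0.08), endothelial and mural (-0.13) and satellite cell (-0.11) means were not the highest. The cause of its low muscle marker mean was not tested. Without wild-type replicate 3 the difference was 0.30 for Ttn and 0.19 for Ryr1, and the fast fibre list was called as lower (adjusted p = 0.0316). Over all arrays, the averaged probe sets gave differences from 0.13 to 1.36 for Ttn, and of 0.06 and 0.93 for Ryr1. The general muscle fibre list was called as higher without wild-type replicate 2 (adjusted p = 0.0360).

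Denervation and regeneration genes were called as a list of 20 measured genes, with a mean difference of 0.21 ± 0.18 (SE; camera adjusted p = 0.0366, and adjusted p = 0.727 with an estimated correlation). Myog, the transcription factor myogenin, rose with the p-values adjusted over the list alone (adjusted p = 0.0297). It measured 0.44 ± 0.21 (SD, n = 3) in mutant and -0.36 ± 0.25 (SD, n = 4) in wild-type muscle, a log2 fold change of 0.80 ± 0.16 or 1.74-fold. Tnnt2, the embryonic and cardiac troponin T, differed by 0.78 ± 0.28, Ncam1 by 0.37 ± 0.22 and Runx1 by -0.28 ± 0.19, and none of the 3 passed. The probe sets averaged for Ncam1 gave differences of 0.02 and 0.71. The call was lost without mutant replicate 1 (difference 0.21, adjusted p = 0.199), mutant replicate 2 (0.13, adjusted p = 0.248), wild-type replicate 2 (0.16, adjusted p = 0.225) or wild-type replicate 3 (0.11, adjusted p = 0.444), and the difference was 0.35 without wild-type replicate 1. Quantile normalization also ended the call (difference 0.21, adjusted p = 0.0921). Wild-type replicate 3, with a 5 prime minus 3 prime value of -0.55 for Gapdh and 0.12 for beta-actin, had the lowest mean of this list at -0.36. Its marker means of other cell types are given above, and the cause was not tested. The 7 satellite cell markers averaged 0.13 ± 0.03 (SE) higher (camera adjusted p = 0.0234, and adjusted p = 0.379 with an estimated correlation). Their exact permutation p was 0.0286, with a permutation adjusted p of 0.486. Their median difference was 0.00, and 4 of the 7 were positive. Sdc4, a heparan sulfate proteoglycan, rose with the p-values adjusted over the list alone (adjusted p = 0.00974), by 0.52 ± 0.11 or 1.43-fold, and Notch3, also expressed in mural cells, differed by 0.31 ± 0.10 and did not pass. The other members named by the rule were Myf5 at 0.15 ± 0.12 and Vcam1 at -0.05 ± 0.08. A second Sdc4 probe set in a lower level class differed by 0.53 ± 0.65. The call was lost without mutant replicate 1 (difference 0.11, adjusted p = 0.197), 2 (0.13, adjusted p = 0.0902) or 3 (0.14, adjusted p = 0.0630), and without wild-type replicate 3 (0.10, adjusted p = 0.0654). It was also lost with the mean over all probe sets (0.14, adjusted p = 0.0682) and with the first component of the deviations as a covariate (0.13, adjusted p = 0.0623).

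Endothelial and mural cell markers averaged 0.18 ± 0.06 (SE) higher over 11 genes (camera adjusted p = 0.000766, and adjusted p = 0.379 with an estimated correlation), and 10 of the 11 had a positive difference. Flt1 and Kdr, both receptors for vascular endothelial growth factor, differed by 0.26 ± 0.11 and 0.32 ± 0.14, Rgs5, a pericyte marker, by 0.36 ± 0.20, and Esam by 0.18 ± 0.12. In wild-type replicate 3 Rgs5 lay at -0.93, and the 5 prime minus 3 prime value was -0.55 for Gapdh and 0.12 for beta-actin. The marker means of other cell types in this array are given above, and the cause was not tested. Without this array the Rgs5 difference was 0.17. Over all arrays, the probe sets averaged for Rgs5 gave differences of 0.09 and 0.64. Its probe sets in lower level classes gave 0.04 and -0.14. None passed when adjusted over the list alone, and without mutant replicate 2 the list call was lost (adjusted p = 0.0902) at a difference of 0.17.

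Markers of other cell types were not called. Adipocyte markers differed by -0.28 ± 0.39 over 9 genes, leukocyte markers by 0.05 ± 0.30 over 14, fibroblast markers by 0.13 ± 0.42 over 10, nerve markers by -0.09 ± 0.19 over 5, erythroid markers by -0.16 ± 0.22 over 4 and cerebellum markers by -0.04 ± 0.05 over 10, with camera adjusted p from 0.238 to 0.758 and 0 genes passing when adjusted over the list alone. The adipocyte list was called as lower with 3 arrays that stood apart as a block (adjusted p = 0.0448), with -0.79 in the other 4 arrays and 0.16 in these 3, and without wild-type replicate 1 (adjusted p = 0.000823). Without wild-type replicate 3 the leukocyte list (adjusted p = 9.02e-05) and the fibroblast list (adjusted p = 0.00129) were called as higher. The erythroid list had a negative mean and a positive median of 0.03. Among these markers the smallest p-values were those of Plin4 (-0.21 ± 0.13) and Lep (-0.36 ± 0.24) in fat, Itgam (0.18 ± 0.10) and Cd3e (-0.36 ± 0.22) in leukocytes, Postn (1.13 ± 0.98) and Col5a1 (-0.21 ± 0.27) in fibroblasts, Mbp (-0.18 ± 0.10) and Sox10 (-0.21 ± 0.12) in nerve, Alas2 (-0.87 ± 0.70) and Slc4a1 (0.18 ± 0.15) in red cells, and Cbln1 (-0.19 ± 0.13) and Gabra6 (-0.07 ± 0.08) in cerebellum. Without mutant replicate 1 the Postn difference was -0.16, without wild-type replicate 2 that of Alas2 was -0.25, and without mutant replicate 2 that of Cd3e was -0.11. The 4 measured sex-linked genes differed by -0.04 ± 0.05 (camera adjusted p = 0.758), with Kdm5d at -0.07 ± 0.09 and Xist at -0.10 ± 0.25.

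Lipid synthesis genes varied more between wild-type arrays than between genotypes. The 23 measured genes of fatty acid and sterol synthesis differed by -0.04 ± 0.38 (SE; camera adjusted p = 0.889), and their list mean ran from -0.71 in wild-type replicate 1 to 0.87 in wild-type replicate 3. The adipocyte list moved the same way, with -0.72 in replicate 1 and 1.01 in replicate 3. Srebf2 differed by 0.23 ± 0.12 and Acacb by 0.11 ± 0.13. The synthesis list was called as higher without wild-type replicate 3 (adjusted p = 0.0161). Its camera direction over all arrays was higher, opposite in sign to its mean and its median of -0.05.

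The remaining lists were not called. The camera adjusted p was 0.0511 for 22 NRF2 target and antioxidant genes (mean difference 0.08 ± 0.09) and for 17 immediate early genes (0.16 ± 0.20), 0.401 for 20 glycolysis and glycogen genes (0.06 ± 0.09), 0.238 for 45 cytosolic ribosomal protein genes (0.03 ± 0.13), 0.889 for 18 chaperones of the endoplasmic reticulum (-0.04 ± 0.10), 0.758 for 17 clock genes (0.02 ± 0.07, with a median of -0.07) and 0.758 for 16 interferon-stimulated genes (0.03 ± 0.20). No member of these lists passed when adjusted over the list alone. Quantile normalization of the centred values called the NRF2 list (adjusted p = 0.0467) and the cytosolic ribosomal list (adjusted p = 0.0413) as higher. The mean over all probe sets called the immediate early list as higher (adjusted p = 0.0183). Without wild-type replicate 2 the NRF2 list (adjusted p = 0.0150) and the immediate early list (adjusted p = 0.0110) were called as higher, and so were, without wild-type replicate 3, the NRF2 list (adjusted p = 0.0127), the immediate early list (adjusted p = 0.0161) and the cytosolic ribosomal list (adjusted p = 0.00290). The interferon list was called as lower without mutant replicate 1 (adjusted p = 0.0452). The members with the smallest p were Keap1 (0.61 ± 0.27) and Txnrd1 (0.33 ± 0.15) of the NRF2 list, Junb (0.54 ± 0.15) and Egr1 (1.27 ± 0.48) of the immediate early list, Slc2a4 (0.27 ± 0.18) and Pgk1 (-0.16 ± 0.14), Rpl39l (-0.36 ± 0.29) and Rps18 (0.10 ± 0.08), Atf6 (0.15 ± 0.11) and Sel1l (0.16 ± 0.15), Nr1d1 (0.20 ± 0.10) and Npas2 (0.52 ± 0.29), and Mx2 (-0.32 ± 0.15) and Usp18 (0.41 ± 0.21). Without mutant replicate 1 the difference was 0.77 for Egr1 and 0.14 for Usp18. It was 0.27 for Npas2 and -0.07 for Rpl39l without wild-type replicate 3, and 0.06 for Atf6 without wild-type replicate 4. The probe sets averaged for Keap1 gave differences of 0.15 and 1.06 over all arrays. Txnrd1 probe sets in lower level classes gave -0.02 and -0.11.

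**Figure D3:**
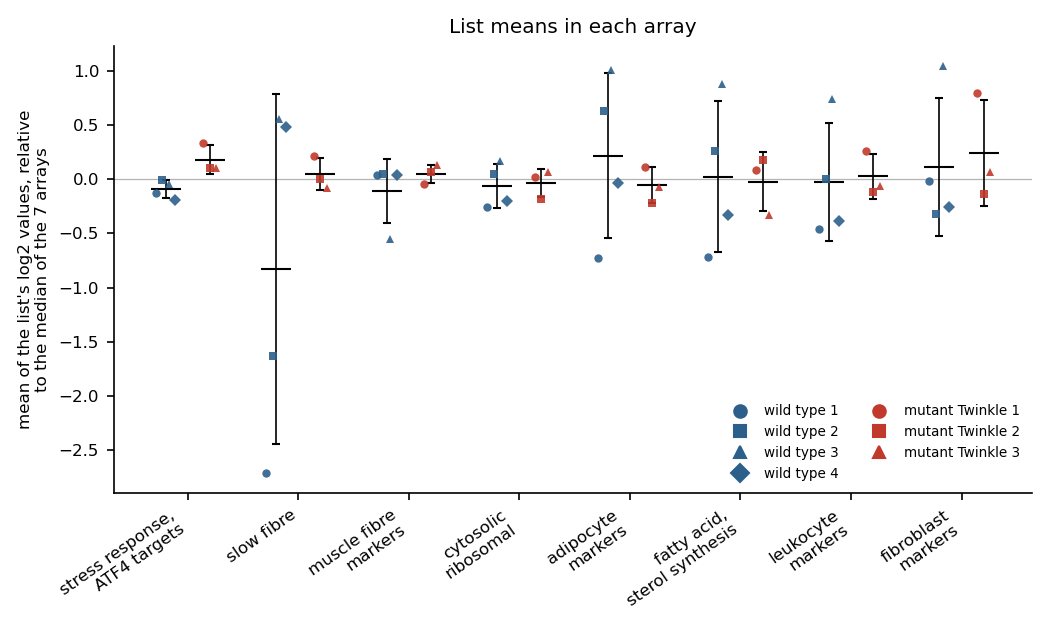
Mean of the log2 values of 8 lists in each array, relative to the median of the 7 arrays (vertical axis), with wild type in blue, mutant Twinkle in red, and black bars at the group mean ± SD. The stress response means of the mutant arrays lie at 0.10 to 0.34 and those of the wild-type arrays at -0.19 to -0.01, while the slow fibre means of wild type run from -2.70 to 0.55.

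Mutant replicate 2 and wild-type replicates 1 and 4 stood apart from the other 4 arrays across genotype. Their cytosolic ribosomal protein means were -0.18, -0.26 and -0.20, against at least 0.02 in the other 4, and the means of complexes III and IV were at most -0.21 against at least 0.04. With these 3 arrays as a block, limma called 0 genes (909 at an unadjusted p under 0.05) and camera 8 lists, 7 higher and 1 lower. The blocked fit called the lists of mitochondrial DNA maintenance (higher, adjusted p = 0.0147) and adipocyte markers (lower, adjusted p = 0.0448), which the fit without a block did not. The stress response list differed by 0.24 within the other 4 arrays (2 against 2) and by 0.26 within these 3 (1 against 2). The Fgf21 difference was 1.63 and 1.17 within the same sets of arrays, and that of Mthfd2 was 1.70 and 1.24. The blocked fit lost the calls of the slow fibre list (adjusted p = 0.0626), the mitochondrial ribosomal list (adjusted p = 0.258) and the satellite cell list (adjusted p = 0.0975).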

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

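The tests of explanations in this part were chosen after the result was seen, although the fit with age as a covariate was itself planned. Among 120 results (named genes and list means), 13 had 1 wild-type array far from the other 3. In these, the gap to the nearest array, divided by the range of the 4, lay above Dixon's critical value for 4 samples. Chance gives about 5.00% for independent, normally distributed results. Here the results share genes and arrays, and 56.4% of probe sets had 2 or more arrays at exactly 0. The 13 are therefore flags and cannot be weighed against 5.00%. Of the 13, 7 concerned wild-type replicate 3, 3 replicate 4, 2 replicate 2 and 1 replicate 1.

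In wild-type replicate 3 the muscle fibre marker list lay at -0.55 (ratio 0.993), Ttn at -1.26 (0.877), Casq1 at -0.39 (0.894), Tnnt2 at -0.91 (0.832), Rgs5 at -0.93 (0.850), Rpl39l at 1.20 (0.841) and Gabra6 at 0.17 (0.899). In the same array the Gapdh control's 5 prime minus 3 prime value, a sign of RNA quality, was -0.55 against -0.040 to 0.094 in the other 6 arrays, while that of beta-actin was 0.12 against -0.14 to 0.12. Its adipocyte (1.01), leukocyte (0.74), fibroblast (1.04) and nerve (0.48) marker means were the highest of all arrays. Its erythroid (0.08), endothelial and mural (-0.13) and satellite cell (-0.11) means were not, and no cause was tested. In wild-type replicate 4 Dlat lay at 0.16 (0.916), Cd3e at 0.07 (0.837) and Runx1 at 0.30 (0.841). In wild-type replicate 2 Myh2 lay at -0.36 (0.942) and Srebf2 at -0.35 (0.901). In wild-type replicate 1 Cdkn1a lay at 0.00 (0.905), against -0.72 to -0.65 in the other 3 wild-type arrays. The control probe sets for 18S ribosomal RNA, which the comparison of genes did not use, averaged 3.19 in mutant replicate 1 and -0.77 to 0.56 in the other 6 arrays.

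The first pattern weighed is the slow fibre list, higher by 0.87 ± 0.81 in mutant muscle. Genotype alone did not set the level, since wild-type list means ran from -2.70 to 0.55, with 2 of the 4 above all 3 mutants. A genotype effect beside such differences between mice is not excluded, since so few arrays can overlap when there is one. Wild-type replicates 1 and 2 were the 2 lowest arrays for 9 of the 12 slow fibre genes. A smaller share of slow fibres in these 2 samples may account for the difference, as a hypothesis found on the same data.

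The second pattern is the integrated stress response list, higher by 0.27 ± 0.09 in mutant muscle. Mutant replicate 1 as the whole cause is argued against, since the difference without it was 0.19. The other mutant arrays both lay at 0.10, above every wild-type array, of which the highest was at -0.01. The separation of 3 arrays from the other 4 as the whole cause is argued against too, since the smaller of the differences within these sets of arrays was 0.24. These differences rest on few arrays and are given without an error. In size the difference was the largest of the 35 splits of the arrays, and the next was 0.25. A straight-line effect of age as the whole cause is argued against, since with age as a covariate the difference was 0.28 (limma camera adjusted p = 1.06e-05, with 1.71e-07 to 0.519 over the alternatives), while other differences between the mice stay open and untested.

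The third pattern is the set of 3 arrays of both genotypes with low ribosomal protein genes, mutant replicate 2 and wild-type replicates 1 and 4. RNA degradation stays open, since the 5 prime minus 3 prime value of the Gapdh control was 0.0039, -0.040 and 0.094 in these 3 arrays, among values of 0.022, 0.033, -0.038 and -0.55 in the other 4, and its spread between repeats is unknown. Hybridisation efficiency stays open too. The spike-in mean was 0.404, -0.145 and 0.252 in these 3 arrays and -0.0436, 0.101, -0.0796 and -0.175 in the other 4. The 2 highest values belong to these 3 arrays, the third lies low, and the spread between repeats is unknown. Age as the whole cause is argued against, since mice of 24 months stood in both sets. A share of age stays open, since the mouse of 26 months was among these 3 and both mice of 21 months among the other 4. No biological explanation was tested, and the source of the pattern stays open.

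The real split called 0 genes with limma, so that 35 of 35 splits gave as many was fixed in advance and says nothing about chance. At an unadjusted p under 0.05 the real split had 264 genes, and 27 of 35 splits had as many. The highest other split gave 1088 genes, with 4361 at an unadjusted p under 0.05. It was the split that sets the same 3 arrays against the other 4. These arrays were grouped after their values were seen to stand apart, so this count is no separate evidence of a structure. With these arrays as a block, the genotype comparison called 0 genes with limma, with 909 at an unadjusted p under 0.05. Chance cannot be excluded for the count of lists either, since the real split gave 9, 21 of 35 splits gave as many and the highest other gave 15. Across genes, which are not independent replicates, the genotype differences within the 3 arrays and within the other 4 had a correlation of -0.066, and 12 of the 18 labelings with the same group sizes gave one as high. Whether 1 genotype effect is shared by both sets of arrays cannot be told apart from none, since 1 mutant array stands in the smaller set.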

How the results depend on the processing

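The block of 3 arrays, the component covariate, the trended prior, the level filter, the test without wild-type replicates 1 and 2 together and the exact permutation test were chosen after the data were seen; the other alternatives were planned. Over all alternatives, 1597 of 1628 values of named genes kept their direction and side of the threshold, 1 passed it and 30, of 23 genes, reversed. For the 9 called lists 111 of 162 values did so, 49 no longer passed and 2 reversed. The shift of every array to 1 median changed nothing, since each array's median was already 0, so its values count as kept. No gene passed in the main fit, so staying on that side of the threshold says little. Of the 25 lists not called, 14 were called in at least 1 alternative. Leaving out 1 array moved the difference of 59 of the 86 named genes by over 1.5 times or turned its sign. The difference of Fgf21 stayed between 1.06 and 1.70 and that of Mthfd2 between 0.91 and 1.85.

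With limma, 0 genes passed in each alternative (100 to 909 at an unadjusted p under 0.05) except array weights, with 1 gene, Myog (adjusted p = 0.0440, 4776 unadjusted, and an adjusted p up to 1.00 in the other alternatives); there mutant replicate 3 had a weight of 14.5 and the others 0.247 to 2.27. The lists called were 0 with an estimated correlation, 0 with fry, 0 with the exact permutation test and 15 without wild-type replicates 1 and 2, and 1 to 13 when each array was left out in turn. The cause was not tested.

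Reversed values were as follows, and the cause was not tested. Quantile normalization gave Twnk -0.018. The mean over all probe sets gave Mbp 0.15, Xist 0.36, Runx1 0.029 and Vcam1 0.024. Array weights gave Twnk -0.13, Mki67 -0.14, Cbln1 0.0029, Ndufb10 -0.019, Atpaf1 -0.079, Sel1l -0.061, Slc4a1 -0.039, Myh2 -0.16, Slc7a5 -0.026, Sars -0.023, Ncam1 -0.038 and Vcam1 0.010. Without wild-type replicates 1 and 2 the slow fibre list was -0.47, Casq1 0.016, Myh7 -0.49, Tnnt1 -0.52, Myl2 -0.51 and Myl3 -0.51. With each array left out in turn the ranges were -0.026 to 0.13 for the mitochondrial ribosomal list, -0.13 to 0.17 for Twnk, -0.019 to 0.31 for Sco1, -0.010 to 0.29 for Slc4a1, -0.16 to 1.87 for Postn, -0.38 to 0.021 for Col5a1 and -0.26 to 0.13 for Xist.

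The replicate number as a block called 0 genes and 9 lists. Mutant and wild-type arrays of the same number had correlations across genes of -0.47, -0.28 and 0.13, which gave no sign of pairing. These correlations cannot exclude it, and the labels do not say whether a number pairs mice. Ages of the same number were 24 and 26, 24 and 24, and 21 and 21 months. The planned offsets before taking logs were not run because the values are already log2, and the planned filter on mean level was not run because centring removed the levels. Signal over background is unknown for the same reason.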

Other observations

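All genes in this part were chosen after their values were seen, and no explanation was tested. Ucp1, the uncoupling protein of brown fat, lay at -3.19 in wild-type replicate 1 and 3.58 in replicate 3, and Cidea, a lipid droplet protein, at -3.22 and 3.59. Elovl6, a fatty acid elongase, lay at -3.35 and 2.69, Thrsp at -2.30 and 2.43, and Fasn, the fatty acid synthase, at -2.17 and 1.75 in the same arrays. The difference between genotypes was -0.91 ± 1.45 (SE) for Ucp1 and -0.05 ± 0.86 for Fasn. In wild-type replicate 3 the leukocyte list mean was 0.74 and the fibroblast list mean 1.04, and in mutant replicate 1 the fibroblast list mean was 0.79, with Postn at 3.82.

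Ino80d, a subunit of a chromatin remodelling complex, had the smallest p of the 18193 genes, with a log2 fold change of 0.91 ± 0.16 (SE), and it did not pass over all genes (adjusted p = 1.00). Smarca4, the ATPase of another remodelling complex, differed by 1.02 ± 0.20, and the nuclear RNA Malat1 by 1.02 ± 0.29, with all 3 mutant arrays above all 4 wild-type arrays for each of these genes. Cyp2e1, a cytochrome P450, differed by -1.39 ± 0.58, with 2.01 and 2.12 in wild-type replicates 2 and 3 and 0.00 and 0.09 in replicates 1 and 4. Cox8b, a subunit of complex IV, lay at -1.61 in mutant replicate 2, -1.41 in wild-type replicate 1 and -1.18 in wild-type replicate 4, and at 0.00 to 0.21 in the other 4 arrays.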
